A study of Caenorhabditis elegans with 2 samples.

How the data were processed

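Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on eGFP-tagged NHR-28, a nuclear hormone receptor, in whole Caenorhabditis elegans larvae of the L4 stage. Per the labels, the strain carries an integrated transgene for the tagged receptor in an unc-119 mutant background, and animals of both sexes were pooled. There were 2 samples in 1 group, and the labels number them as biological replicates 1 and 2. No control sample was analysed here.

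Per the file headers and the deposited file descriptions, regions were called against a control alignment for each replicate and for the pooled alignments, keeping weak background regions for the irreproducible discovery rate (IDR) procedure. The authors derived an optimal set from the pooled list and both replicate lists. The peak caller, its version and the IDR threshold are not given in the sources used here. Each list was deposited on the ce11 and ce10 builds, and ce11 was used for all main results. In the deposited lists, the signal value of each region is the authors' own, and its scale is not given in the sources used here. It was used to describe, rank and filter regions within a list and to compare gene lists within a list. Between the replicate lists, signal was compared by correlation and by rank percentile, and single values from both are given side by side without a test. The deposited −log10 q value reached a ceiling of 4.32 in the pooled list, which 10560 regions shared, so regions could not be ranked by it. The optimal set held 8745 regions, which were the 8745 pooled regions of highest signal, and all of them had the maximal −log10 q. In the optimal set, 30 entries shared their coordinates with another entry and differed in the summit. A summit offset lay beyond the end of its region in 1 optimal entry, and it was set to the last base. Read counts per library were not analysed here, so the depth behind each region is unknown. No optimal region reached beyond a chromosome end of the WBcel235 reference.

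Coordinates are 1-based on ce11 (WBcel235), with genes from Ensembl release 115. A promoter ran from 1000 bp upstream to 200 bp downstream of any annotated transcription start site (TSS) of a protein-coding gene. Summits were placed in promoters, then 5′ UTRs, coding exons, 3′ UTRs, introns, genes of other types and intergenic sequence, in that priority. The shares were compared with 1000 circular shifts of all summits within chromosomes. The smallest two-sided p that 1000 shifts can give is 0.002. Replicate lists were compared by the share of the top 8745 regions by signal that overlapped by at least 1 bp. Each optimal peak was matched, in each replicate list, to the region of highest signal that covered its summit.

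The 28 gene lists were fixed by gene symbol before the data were examined, as were the 15 sequence motifs. Some marker lists took in whole symbol families, such as the puf genes (germline) and pqn genes (pharynx). The name of a list therefore need not hold for each member. Each list was tested by Fisher's exact test, two-sided, on protein-coding genes with and without an optimal promoter summit, with Benjamini-Hochberg adjustment over the 28 lists. Some genes belong to more than 1 list. The signal of the highest promoter summit per gene was compared between a list and all other genes with a summit by a two-sided permutation test of medians with 100000 resamples, whose smallest p is 1e-05, for lists with at least 5 such genes. Motifs and 6-mers were searched on both strands within 50 bp of each summit and in a window of equal width 500 bp to one side, the side being drawn with a fixed seed. The difference was tested by an exact two-sided binomial test on discordant pairs, with Benjamini-Hochberg adjustment. Genes and regions are not independent replicates, so these p-values describe the regions of this set and not the spread between animals.

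Named items followed a rule fixed before the data were examined. These were the 15 optimal peaks of highest signal, 4 members of highest promoter signal for each list past an adjusted p of 0.05 and 2 for each other list, nhr-28 and unc-119, all 15 motifs, the 10 leading 6-mers by p, and the 5 peaks in each direction that differed most in rank percentile between replicates. For the 15 highest peaks and those that differed most between replicates, the nearest TSS gave the name where a peak lay in several promoters. List members were named wherever their own promoter held the summit, even if the TSS of another gene was nearer. Of all promoter summits, 18.8% lay in promoters of 2 or more genes.

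Alternatives changed the promoter window (500 bp upstream to 100 bp downstream, or 2000 bp upstream to 500 bp downstream), the number of peaks, the overlap rule, the null, the gene background, the motif and flank windows and the build, and left out each replicate. Mappability, the length of the upstream gap, base composition, the wider set of all regions at the maximal −log10 q, the single-replicate tests of the X chromosome and the test of TGATAA outside promoters were added after the data were examined. Promoter mappability was the share of 32-mers found once in the nuclear genome. The tests of lists, locations, motifs, 6-mers, replicate overlap and signal were tested on simulated data, and those added later were not. The list test recovered 96% of calls simulated at an odds ratio of 4 over 19973 genes, and 0.5% of unchanged lists were called. In that simulation each gene was drawn independently, so neither rate covers summits shared by neighbouring genes. Only lists of intermediate size were changed, so the recovery does not cover the smallest and largest lists. In the test of lists against circular shifts, odds ratios were ranked without a continuity correction, so that a list at 0 ties with shifts at 0. That rule replaced a continuity correction after the first values of the test had been seen. The change ended the calls of major sperm proteins and vitellogenins in that test. With the rule used, 5.71% of unchanged simulated lists had an unadjusted permutation p under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. A list by IDR value was not analysed here because the score column of each list held a single value.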

Results

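The data were peak lists from 2 biological replicates of eGFP-NHR-28 ChIP-seq in L4 larvae, a list from their pooled alignments and an optimal set from all of them. Each replicate list held 30000 regions and the pooled list 29697. The optimal set held 8745 regions with a median width of 350 bp and a median signal value of 72.7, ranging from 36.2 to 993. The labels name the tagged receptor and the stage, so the comparisons concern where the regions lay, which genes they marked and how far the replicates shared them.

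The optimal peaks of highest signal lay at promoters of genes for conjugating enzymes, nuclear hormone receptors and a cytochrome P450. The highest, with a signal of 993, spanned II 9586786 to 9587225 (ce11) and had its summit in the promoter of ugt-58, a UDP-glucuronosyltransferase gene. Its signal was 559 in replicate 1 and 437 in replicate 2. The next was in the promoter of nipi-3, a Tribbles-family kinase gene (X 15607422 to 15607950, signal 982). Promoters of ugt-64 (840) and ugt-8 (681) were also among the 15 highest, as were those of nhr-202 (715), nhr-237 (692), nhr-256 (690) and nhr-178 (644), cyp-33A1 (657) and the uncharacterised F59B1.8 (752). The other 5 of the 15 lay outside promoters. An intergenic peak lay at I 13475461 to 13475876 (830) and another at X 6255492 to 6255983 (703). Intronic peaks lay at IV 1624310 to 1624927 (804), where the nearest TSS was that of nhr-87, and at IV 13075548 to 13076062 (674), nearest to C39E9.7. A peak at I 4701042 to 4701789 (645) lay in a gene of another type. Ranks in the replicate lists ran from 1 to 19 for all 15.

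Regions of the replicates coincided far more than shifted lists did. Of the top 8745 regions of replicate 1, 7164 (81.9%) overlapped a top region of replicate 2, against a mean of 5.50% and a maximum of 7.79% over the shifts (two-sided permutation p = 0.002, the smallest the shifts can give). In the other direction the share was 81.7%. Of the optimal peaks, 8557 (97.9%) had a region over their summit in both replicates, and 6891 (78.8%) ranked within the top 8745 of both. These shares are no independent measure of agreement, since the optimal set came from the same replicates. Besides, the replicate lists kept weak background regions. Across the 8557 peaks with a region in both, signal correlated between replicates with a Spearman rho of 0.714. The Pearson r was 0.726 on the log2 scale, and peaks are not independent replicates. Among the 4242 of lower pooled signal the rho was -0.079. The optimal set was chosen on pooled signal, and such a cut can lower the correlation between replicates. The size of this effect was not tested.

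**Figure D1:**
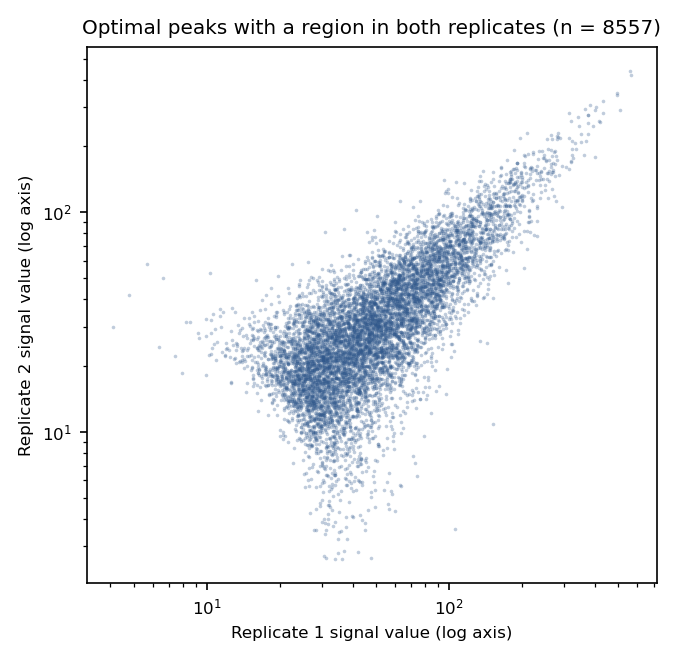
Signal value in replicate 1 (x axis) and replicate 2 (y axis) of the 8557 optimal peaks with a region over their summit in both lists, both on log axes, with 1 point per peak. The points run along a diagonal at high signal, and spread at low signal, with a Spearman rho of 0.714.

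The peaks that differed most between replicates were matched to a region of low rank in one list. The largest difference in rank percentile was 81.6 points, for a peak in the promoter of T24D5.4 (X 12595997 to 12596346), whose signal was 47.6 in replicate 1 and 2.65 in replicate 2. Those next higher in replicate 1 lay upstream of glb-5, a globin gene (76.8 points), in intergenic sequence at X 16726859 to 16727189 (76.0) and V 13046191 to 13046540 (76.0), and in an intron at V 3655368 to 3655717 near acr-23 (75.4). In the other direction, a peak in the promoter of ndg-4 (III 4467367 to 4467716) had a signal of 4.08 in replicate 1 and 30.1 in replicate 2. It was followed by an intergenic peak at II 5321970 to 5322319, a peak in the promoter of ZK673.2 (II 10447459 to 10447631) and intergenic peaks at I 7659312 to 7659661 and III 10537648 to 10537997. The median absolute difference over the set was 4.31 percentile points, and 44 peaks differed by more than 50. Only regions covering the optimal summit were matched, so a stronger region beside it in the same replicate would be missed. Whether that holds for these peaks was not examined, so a low value need not mean weak signal at the locus.

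Promoters held more summits than under the shifts. Of the 8745 summits, 4645 (53.1%) lay in a promoter, against 26.0% ± 0.522 (SD over 1000 shifts; permutation adjusted p = 0.00233). With the window of 500 bp upstream to 100 bp downstream the share was 41.3% against 14.1%. Coding exons held 1.76% against 18.8% in the shifts, and introns 16.8% against 27.2%. The shares were 1.01% against 2.38% for 3′ UTRs and 2.41% against 3.42% for genes of other types (each of these classes, permutation adjusted p = 0.00233). Genes of other types were not alike: by summits within 200 bp, tRNA genes were above the shifts and pseudogenes and piRNA genes below, as given under other observations. By any overlap of the region in place of the summit, the 3′ UTR call ended (1.78% against 1.75%, permutation adjusted p = 0.825). The coding exon fold was then 0.224, against 0.0937 by summit. Intergenic sequence held 24.5% against 21.8% (permutation adjusted p = 0.00233). That call ended with the widest promoter window (0.983 times the shifts, permutation adjusted p = 0.585), which assigns more summits to promoters. The share in 5′ UTRs outside promoters, 0.412%, did not differ past the threshold (permutation adjusted p = 0.947). The median promoter summit lay 189 bp upstream of the TSS (-189 bp), and 57.1% lay within 300 bp upstream. A promoter summit was found for 4946 of 19973 protein-coding genes (24.8%).

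Genes on the X chromosome carried promoter summits more often than autosomal genes. They were 776 of 2731 (28.4%), against 24.2% of autosomal genes (odds ratio 1.24, Fisher's exact two-sided p = 2.57e-06, adjusted over 6 chromosomes 1.54e-05). Each autosome was set against all other chromosomes after the data were examined. Chromosomes III (27.5%, exact adjusted p = 0.00128) and I (26.3%, exact adjusted p = 0.0400) were above the others, and IV (odds ratio 0.835, exact adjusted p = 0.000204), V (23.2%, exact adjusted p = 0.00639) and II (23.3%, exact adjusted p = 0.0361) below them. Peaks per Mb ran from 72.1 on IV to 103 on X.

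Detoxification, lipid and intestinal genes had promoter summits far more often than other genes. UDP-glucuronosyltransferase genes, whose enzymes conjugate sugars to small molecules, had one in 52 of 67 (77.6%, odds ratio 10.6, Fisher's exact adjusted p = 1.27e-18), led by ugt-58, ugt-64, ugt-8 and ugt-49 (576). Cytochrome P450 genes had one in 47 of 74 (63.5%, odds ratio 5.33, exact adjusted p = 1.07e-11), led by cyp-33A1, cyp-34A9 (410), cyp-29A2 (383) and cyp-33C5 (344). Glutathione S-transferase genes had one in 23 of 49 (odds ratio 2.70, exact adjusted p = 0.00159), led by gst-5 (381), gst-33 (332), gst-7 (270) and gst-42 (255). Fatty acid and lipid metabolism genes had one in 60 of 103 (58.3%, odds ratio 4.28, exact adjusted p = 4.35e-12), among them ech-1.2 (609), daf-22, a peroxisomal thiolase gene (580), cpt-2, a carnitine palmitoyltransferase gene (456), and acs-2, an acyl-CoA synthetase gene (320). Intestine markers had one in 27 of 33 (81.8%, odds ratio 13.7, exact adjusted p = 4.13e-11), led by cpr-9 (465), erm-1 (307), cpr-3 (304) and lys-8 (239). Nuclear hormone receptor genes, the family of NHR-28 itself, had one in 114 of 274 (41.6%, odds ratio 2.19, exact adjusted p = 3.20e-09), led by nhr-202, nhr-237, nhr-256 and nhr-178.

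Genes for general cell functions formed a further set with more summits. Cytosolic ribosomal protein genes had one in 65 of 79 (82.3%, odds ratio 14.3, Fisher's exact adjusted p = 1.05e-25), led by rpl-3 (588), rpl-15 (424), rpl-35 (391) and rps-13 (359). Translation factors had one in 19 of 38 (odds ratio 3.05, exact adjusted p = 0.00177), led by eef-1G (282), eef-1A.1 (221), eef-1A.2 (214) and eef-2 (207). The mitochondrial respiratory chain and ATP synthase list had one in 23 of 45 (odds ratio 3.19, exact adjusted p = 0.000521), led by ucr-2.1 (355), cox-5B (234), cox-5A (218) and atp-3 (205). The vacuolar ATPase had one in 13 of 21 (odds ratio 4.95, exact adjusted p = 0.000849), led by vha-8 (232), vha-12 (224), vha-1 (202) and vha-13 (169). No region of replicate 2 covered the summit at vha-12, where the promoter summit of that replicate belonged to a region of rank 515. Heat shock protein and chaperone genes had one in 29 of 60 (odds ratio 2.85, exact adjusted p = 0.000255), led by hsp-110 (254), dnj-20 (213), hsp-3 (196) and hsp-1 (195). Proteasome genes had one in 17 of 33 (odds ratio 3.24, exact adjusted p = 0.00177), led by rpn-3, which shares its peak with hsp-110, pbs-2 (134), rpn-6.1 (100.4) and pbs-3 (89.5). When each summit was given only to its nearest TSS, ribosomal protein genes fell to 39 of 79 (odds ratio 3.72, exact adjusted p = 1.03e-07) and the chaperone call ended (exact adjusted p = 0.205). The vacuolar ATPase odds ratio was 13.1 with the wide window, and the proteasome call ended among the 4372 peaks of highest signal (odds ratio 1.40, exact adjusted p = 0.542).

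Chemoreceptor, neuronal, sperm and histone genes had fewer promoter summits. Of 1258 chemoreceptor genes, 42 (3.34%) had one (odds ratio 0.0973, Fisher's exact adjusted p = 1.63e-100), the highest being at str-7 (298), srz-62 (297), srr-4 (263) and srh-2 (263). Neuron markers had one in 4 of 61 (odds ratio 0.213, exact adjusted p = 0.00112), namely snb-1 (105), egl-21 (51.8), rab-3 (42.4) and mec-3 (37.6). Of these, rab-3 had no summit without replicate 1, mec-3 had none without replicate 2, and egl-21 and mec-3 had none with the narrow window, and the list's odds ratio ran from 0.105 among the peaks of highest signal to 0.375 with the wide window. Major sperm protein genes had one in 0 of 31, with an upper Wilson 95% bound of 11.03% (exact adjusted p = 0.000631). Histone genes had one in 8 of 72 (odds ratio 0.379, exact adjusted p = 0.0102), with his-37 (405), his-3 and his-4 at a shared peak (92.9) and his-24 (80.9). Of the histone promoters, 10 of 72 were at least 90% unique, as was 1 of the 31 sperm protein promoters, so a lack of regions there is uncertain. The histone call ended without replicate 1 (exact adjusted p = 0.104), without replicate 2 (0.0677), with the narrow window (0.115), and among the peaks of highest signal (0.0616), as it did against circular shifts (permutation adjusted p = 0.550). The call of the sperm protein genes also ended against circular shifts (permutation adjusted p = 0.241). For that list the result rests on ranking without a continuity correction, a rule set after the first values of the test had been seen.

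**Figure D2:**
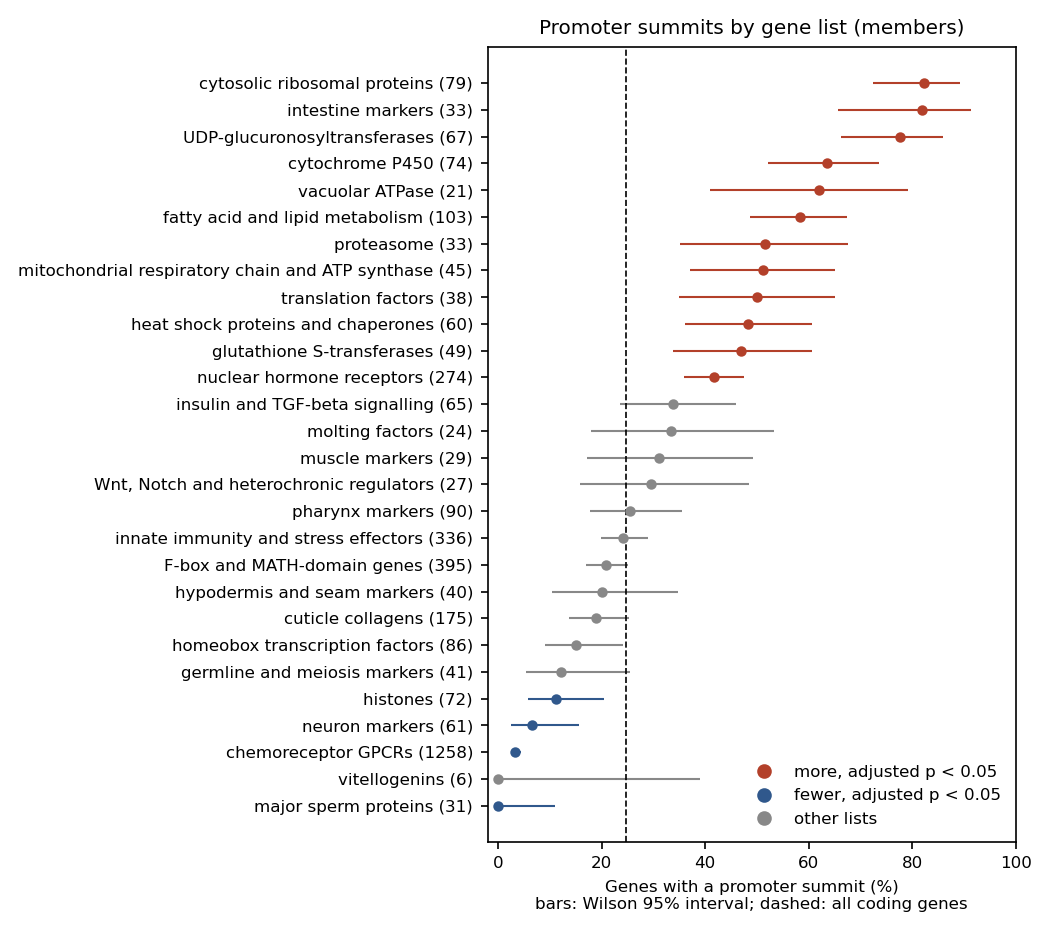
Share of each list's genes with an optimal promoter summit (x axis, percent), with Wilson 95% intervals and the number of members in brackets. The dashed line marks all protein-coding genes (24.8%), and coloured points are the 12 lists above and the 4 below it at an adjusted p under 0.05.

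The other 12 lists did not pass the test. Homeobox genes had summits at 13 of 86 (Fisher's exact adjusted p = 0.0727), with ceh-38 (268) and ceh-99 (128) highest. F-box and MATH-domain genes had them at 82 of 395 (exact adjusted p = 0.102; bath-36 284, fbxc-29 243), germline and meiosis markers at 5 of 41 (exact adjusted p = 0.102; puf-9 483, cgh-1 143) and cuticle collagens at 33 of 175 (exact adjusted p = 0.109; col-38 152, col-149 135). Insulin and TGF-beta signalling genes had them at 22 of 65 (exact adjusted p = 0.149; akt-2 264, sma-2 229), molting factors at 8 of 24 (exact adjusted p = 0.422; myrf-1 144, nhr-25 72.9) and muscle markers at 9 of 29 (exact adjusted p = 0.464; act-1 95.9, act-4 85.7). Vitellogenins had 0 of 6 (exact adjusted p = 0.422). Wnt, Notch and heterochronic regulators had them at 8 of 27 (exact adjusted p = 0.573; lin-28 211, lin-14 128), hypodermis and seam markers at 8 of 40 (exact adjusted p = 0.629; ajm-1 74.6, nhr-25 72.9), innate immunity and stress effectors at 81 of 336 (exact adjusted p = 0.880; clec-72 399, spp-8 302) and pharynx markers at 23 of 90 (exact adjusted p = 0.903; pqn-42 162, peb-1 155). Some of these lists passed under other settings, such as homeobox genes with the narrow window (odds ratio 0.305, exact adjusted p = 0.00296), F-box and MATH-domain genes (0.512, exact adjusted p = 0.000569) and collagens (0.379, exact adjusted p = 0.00263) among the peaks of highest signal, and insulin and TGF-beta genes by nearest TSS (1.94, exact adjusted p = 0.0260). Wnt, Notch and heterochronic regulators passed with the wide window, above other genes (15 of 27, odds ratio 2.72, exact adjusted p = 0.0178). Germline markers were below others with named genes as background (odds ratio 0.340, exact adjusted p = 0.0217).

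Signal at the promoters with a summit was also higher in 5 of the lists. The median was 133 in nuclear hormone receptor genes against 78.3 in other genes, 128 in ribosomal protein genes, 126 in UDP-glucuronosyltransferase genes, 124 in cytochrome P450 genes and 106 in lipid genes (permutation adjusted p = 0.000125, 0.000125, 0.000167, 0.000562 and 0.0125, the first a pair from the smallest p that the resamples can give). No list was lower at an adjusted p under 0.05, and at an unadjusted p under 0.05 F-box and MATH-domain genes were (0.823 times the others, permutation p = 0.0406, adjusted 0.121). Hypodermis and seam markers (8 genes, permutation adjusted p = 0.219) were lower when pooled rank replaced signal (permutation adjusted p = 0.0292). Intestine markers had a median of 110 (permutation adjusted p = 0.0622), and passed in the signal of replicate 1 alone (permutation adjusted p = 0.0127) but not of replicate 2 alone (0.213). Heat shock and chaperone genes (permutation adjusted p = 0.212) passed in the signal of replicate 2 alone (ratio 1.59, permutation adjusted p = 0.00642).

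The GATA sequence TGATAA was the fixed motif with the lowest p. It occurred within 50 bp of 2910 summits (33.3%) and in 917 flank windows (10.5%), a fold of 3.17 (exact binomial adjusted p = 1.23e-294). The GAGA repeat GAGAGAGA rose from 0.766% to 5.61%, CCGCCC from 1.42% to 4.20%, CACGTG from 1.85% to 4.60% and GTAAACA from 1.27% to 2.61% (exact adjusted p = 1.11e-82, 5.95e-29, 5.18e-25 and 2.20e-10). The nuclear receptor half-site AGGTCA was at 4.38% of summits and 2.79% of flanks (fold 1.57, exact adjusted p = 2.93e-08), whereas the half-site AGTTCA was less frequent at summits (5.98% against 7.43%, exact adjusted p = 0.000172). CAGCTG (2.85% against 1.97%) and TGASTCA (1.51% against 1.07%) were higher (exact adjusted p = 0.000250 and 0.0141). TTTCAG (7.15% against 19.4%), TAATTA (1.68% against 5.27%) and TATAAA (7.49% against 12.5%) were lower (exact adjusted p = 7.14e-128, 6.57e-39 and 7.59e-28). The sites of HNF4 type, CAAAGTCCA (11 summits, 8 flanks) and AAGTCCA (44 and 64), did not differ past the threshold (exact adjusted p = 0.694 and 0.0773), nor did TGACGTCA (58 and 55, exact adjusted p = 0.851). Calls of some motifs depended on the setting. That of TGASTCA ended with windows of 25 bp to each side (exact adjusted p = 0.899), with flanks at 250 bp (0.190) and 1000 bp (0.0848), among the peaks of highest signal (0.163) and without replicate 1 (0.122). That of CAGCTG ended with flanks at 1000 bp (exact adjusted p = 0.279) and without replicate 1 (0.0509). That of AGTTCA ended when the 4645 promoter summits alone were set against promoters of genes without a summit (fold 0.857 against 0.805, exact adjusted p = 0.0736). AAGTCCA was called less frequent with windows of 100 bp (exact adjusted p = 0.00414), with flanks at 250 bp (0.0176) and 1000 bp (0.00179) and without replicate 1 (0.0193). With flanks at 250 bp, CAAAGTCCA was called more frequent (11 summits, 2 flanks, exact adjusted p = 0.0259), and TGACGTCA was called more frequent without replicate 1 (exact adjusted p = 0.0246).

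Set against 6-mers of the same base composition, a comparison chosen after the data were examined, AGGTCA did not stand out. Its fold of 1.57 lay below the 95th percentile of 1.84 of the other 179, as did that of CAGCTG (1.45, below 2.41). CACGTG (2.48, above 2.33), CCGCCC (2.96, above 2.59, with 5 others) and TGATAA lay above theirs. Of the motifs less frequent at summits, TTTCAG, the 3′ splice acceptor sequence, lay below its 5th percentile (0.368, below 0.578). TAATTA (0.319, above 0.304), TATAAA (0.601, percentile 85.7) and AGTTCA (0.805, percentile 41.6) did not stand out. Summits lay in introns and coding exons less often than under the shifts, and base composition does not control for that. Whether this position in genes lowered TTTCAG was not tested.

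**Figure D3:**
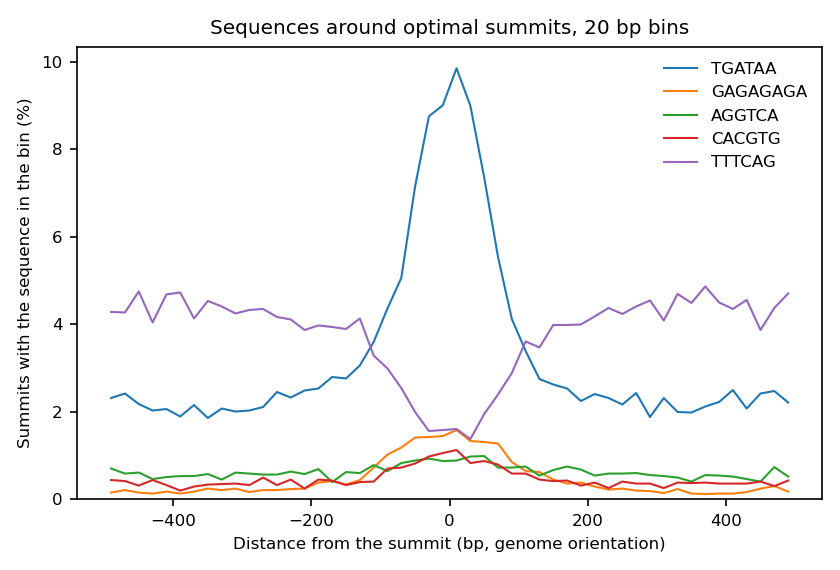
Share of optimal summits (y axis, percent) with each of 5 sequences in bins of 20 bp by distance from the summit (x axis, bp). TGATAA reaches 9.85% in the bin just past the summit, and TTTCAG dips around it.

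Among all 2080 6-mers, 891 were more and 597 less frequent at summits (exact binomial test, adjusted p under 0.05). The 10 leading by p were AAAATT (fold 0.416), CTTATC (5.16), TGATAA (3.17), GAGAGA (4.24), AAAAAT (0.527), TTAAAA (0.344), AAATTT (0.350), AGAGAG (4.08), TTTAAA (0.253) and AAATTA (0.365). Summit windows were 41.3% G and C and flank windows 34.9%.

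TGATAA was spread unevenly over the gene lists, a comparison chosen after the data were examined and made for 4 sequences over 25 lists. No list passed for GAGAGAGA (lowest exact adjusted p = 0.391), AGGTCA (0.860) or CACGTG (1), and at an unadjusted p under 0.05 there were 2 for GAGAGAGA, pharynx markers (4 of 25 summits) and innate immunity genes (0 of 85), and 0 for the others. Promoter summits of intestine markers carried it in 28 of 32 (87.5%, Fisher's exact adjusted p = 3.02e-09), those of innate immunity genes in 55 of 85 (64.7%, exact adjusted p = 8.13e-09), of F-box and MATH-domain genes in 50 of 81 (61.7%, exact adjusted p = 3.06e-07) and of UDP-glucuronosyltransferase genes in 33 of 59 (55.9%, exact adjusted p = 0.000715), with insulin and TGF-beta genes (16 of 28, exact adjusted p = 0.0184) and lipid genes (36 of 74, exact adjusted p = 0.0101) also above others. Ribosomal protein genes carried it in 1 of 64 summits (exact adjusted p = 8.13e-09), the respiratory chain list in 0 of 23 (exact adjusted p = 0.000715), chaperone genes in 1 of 32 (exact adjusted p = 0.000421), translation factors in 1 of 19 (exact adjusted p = 0.0261) and the proteasome in 1 of 17 (exact adjusted p = 0.0375). Nuclear hormone receptor genes were also below other promoter summits, at 25 of 129 (19.4%, exact adjusted p = 0.00351). Of the other detoxification lists, cytochrome P450 genes (19 of 48, exact adjusted p = 0.368) and glutathione S-transferase genes (4 of 26, exact adjusted p = 0.150) did not pass the test.

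**Figure D4:**
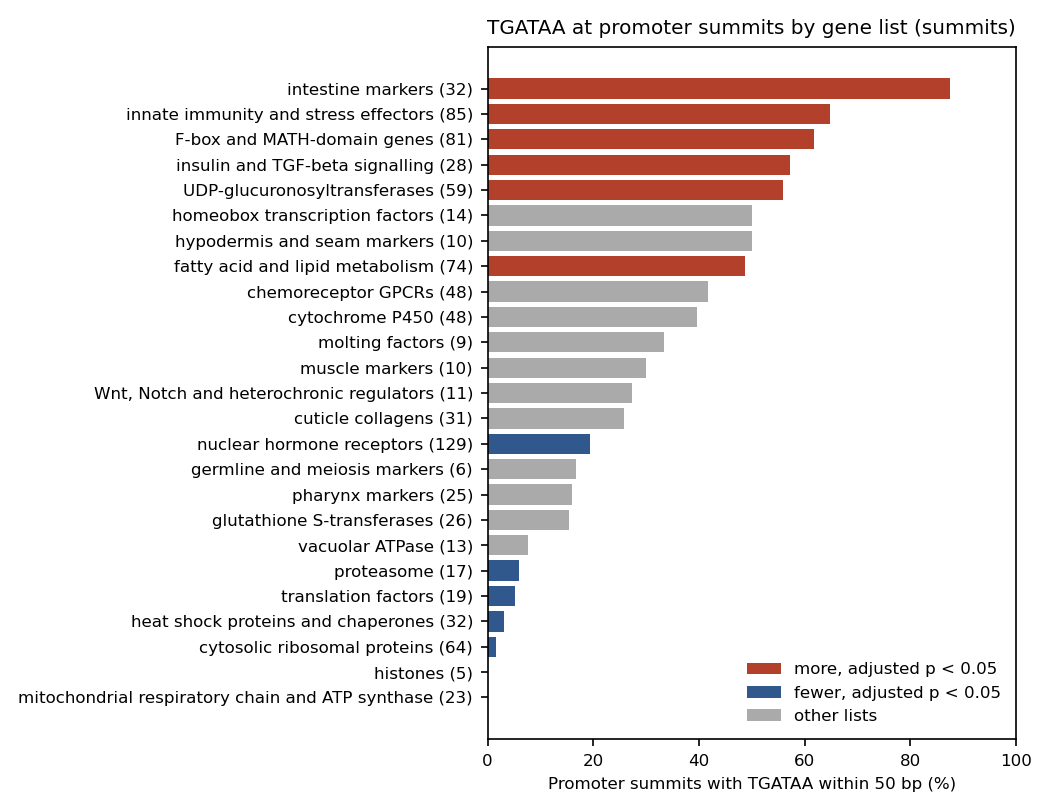
Share of promoter summits with TGATAA within 50 bp (x axis, percent) for each gene list with at least 5 promoter summits, whose number is in brackets. Intestine markers are at 87.5% and ribosomal protein genes at 1.56%; coloured bars passed an adjusted p of 0.05.

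Few regions of the pooled list lay near the tagged gene and the selection marker. No optimal or pooled region had its summit within 20 kb of nhr-28 (X 16354976 to 16359650), where the median X window of that width held 15 pooled summits. Replicate 1 had 1 summit there, of rank 26500, and replicate 2 had 0. Around unc-119 (III 10902641 to 10908935), the optimal set had 0 and the pooled list 1, of rank 27523 and signal 5.98, against a median of 14. Replicate 1 had 2 there. Replicate 2 had 6, the highest at rank 12642 of its 30000, against a median of 15, and 10.9% of windows held as few. Within 10 kb it had 5 against a median of 8, and 30.5% of windows held as few.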

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

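The tests of TGATAA against base composition and outside promoters were chosen after the motif results were seen, and the mappability and gap settings were added after the data were examined. A further 1815 pooled regions outside the optimal set had the same maximal −log10 q, and were noted because they are a signal in data that the comparisons did not use. Of these, 1668 (91.9%) had a region over their summit in both replicates, and 47.2% of their summits lay in promoters, against 26.0% in the shifts and 53.1% in the optimal set. The signal of these 1815 regions ran from 27.9 to 36.2. Since they came from the pooled alignments of the same replicates, the share found in both is no independent measure of agreement.

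For the gene lists, the length of the upstream gap did not account for the pattern, since all 16 called lists kept their direction and call after stratification by gap decile. Reads shared between near-identical copies did not account for the lists with more summits, of which 12 of 12 kept the call among genes with unique promoters. Of the 4 lists with fewer, 2 kept it (chemoreceptor and neuron lists). For the histone and sperm protein lists, lost reads and a true lack of binding cannot be told apart, because few of their promoters are unique, and the 10 histone genes with unique ones had an odds ratio of 1.84 (Fisher's exact adjusted p = 0.586). No biological explanation was tested, since the design holds 1 group. The background was all protein-coding genes, and expression and chromatin state were not analysed here, so lists were not compared at equal expression.

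For TGATAA, base composition did not account for the excess: the other 59 6-mers of the same composition had a 95th percentile fold of 1.11 and a maximum of 1.84, below 3.17. Promoters of intestinal and detoxification genes did not account for it alone, since it was at 34.4% of the 4100 summits outside promoters, against 9.83% of flanks (fold 3.50, exact binomial p = 3.64e-158, 95th percentile of the other 59 there 1.20), and at 34.7% of the 2706 outside the wide window. A candidate explanation for its spread among promoters is that GATA sites go with intestinal and detoxification genes, and in a test fixed before its result was seen 116 of 213 promoter summits (54.5%) of the intestine, UDP-glucuronosyltransferase, P450 and lipid lists had it, against 2 of 81 (2.47%) of the ribosomal and proteasome lists (Fisher's exact two-sided p = 2.36e-19). This stays open, because the compared lists lay far below other promoters and P450 genes (39.6%, exact adjusted p = 0.368) did not pass against other promoter summits (32.2%). Glutathione S-transferase genes, a detoxification list left out of the test, had it in 4 of 26 (15.4%, exact adjusted p = 0.150). Innate immunity (64.7%), F-box and MATH-domain (61.7%) and insulin and TGF-beta genes (57.1%), also left out, lay above 54.5%. Whether NHR-28 or another factor contacts the TGATAA sites was not tested.

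The pooled list held 0 regions within 20 kb of nhr-28 and 1 within 20 kb of unc-119, and 3.03% and 3.02% of windows on their chromosomes held as few. Extra transgene copies of the nhr-28 locus and extra transgene copies of the unc-119 locus were to show as counts above the 95th percentiles of 31 and 29, which were not reached. At loci so low in pooled regions this does not exclude them, since a gain could be hidden by whatever lowered the counts. Extra copies in the sample or in the control alignment and masking by the authors cannot be told apart, because the control was not analysed here.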

How the results depend on the processing

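The settings by mappability, gap strata, all regions at maximal −log10 q and TGATAA outside promoters, and the tests of X in each replicate, were chosen after the data were examined. The share of summits in promoters, the replicate overlap, the excess on X and the numbers of motifs, 6-mers and lists with more summits kept their direction and their side of the threshold, or stayed within 1.5 times, under each alternative run for them. The replicate overlap of 81.9% ran from 65.6% (all regions) to 82.0% (ce10). Spearman's rho was 0.654 in the 4315 matched peaks of the upper part of the set by signal and -0.079 in the 4242 of the lower. Choosing peaks in a narrow range of pooled signal can tie high values in one replicate to low ones in the other. Whether this lowered rho here was not tested. The optimal set falls to 4372 by construction. Lists with fewer summits numbered 7 with the widest promoter window, 8 with named genes as background and 2 against circular shifts, against 4, and the cause was not tested. Lists with lower signal numbered 1 by pooled rank (hypodermis and seam markers), against 0. The share of windows with as few pooled regions as nhr-28 was 3.03% at 20 kb, 8.53% at 10 kb and 25.7% at 50 kb, and for unc-119 3.02% at 20 kb, 11.2% at 10 kb and 1.83% at 50 kb (0.548% in the optimal set).

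Direction changed for these results, and the cause was not tested. The 5′ UTR fold over shifts was 1.20 and 1.22 with the narrow and wide windows, 1.02 in the peaks of highest signal, 0.839 to 1.00 with either replicate left out and 1.01 for all regions at maximal −log10 q. The intergenic fold was 0.983 with the wide window and the 3′ UTR fold 1.02 by whole-region overlap, neither past the threshold (permutation adjusted p = 0.585 and 0.825). List odds ratios were 0.817 (narrow window) and 0.572 (highest signal) for molting factors, 0.511 and 0.786 for Wnt, Notch and heterochronic regulators (but 2.72 with the wide window), 1.02 for innate immunity without replicate 1 and 1.02 by nearest TSS, 0.842 (named background) and 0.993 (gap strata) for pharynx markers, and 0.965 for muscle markers and 1.84 for histones with unique promoters. With either replicate left out, signal ratios were 0.928 at the lowest for innate immunity, 0.961 to 1.05 for glutathione S-transferases and 0.897 to 1.03 for germline markers, and the TGACGTCA fold was 0.982 to 1.55.

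Over all settings, where direction was kept, single lists newly passed the threshold in 19 cases and ceased to in 8, and single motifs in 6 and 8. These counts leave out results that changed direction, such as the histone list with unique promoters, which also lost its call. The rank of a named gene's peak stayed within 1.5 times in 262 cases and moved further in 49. With the narrow window nhr-237, vha-13, acs-2, egl-21, mec-3, cgh-1, ceh-99, str-7, srz-62, fbxc-29 and akt-2 had no promoter summit, as had rab-3 without replicate 1 and mec-3 without replicate 2. The alternative by IDR value was not run because the lists used here hold none per region, nor were the ce10 alternatives at nhr-28 and unc-119, since gene positions on ce10 were not used here. No paired analysis was possible because there is 1 group. Depth is unknown and limits what the lack of a region means.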

Other observations

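Genes for short structured RNAs had optimal summits within 200 bp more often than under circular shifts, in a test chosen after the data were examined, as was the measure of stretches without summits that follows. Summits lay near 193 of 612 tRNA genes (31.5%, against 4.33% in the shifts), 83 of 346 snoRNA genes (24.0%, 5.21 times the shifts) and 17 of 129 snRNA genes (13.2% against 4.31%), each with a permutation adjusted p of 0.00233. Long intergenic RNA genes (52 of 194, 26.8% against 12.2%, permutation adjusted p = 0.00233) and microRNA genes (22 of 261, 8.43% against 4.42%, permutation adjusted p = 0.0140) were also above the shifts. Pseudogenes (69 of 2128, 3.24% against 13.4%) and piRNA genes (148 of 15363, 0.963% against 3.03%) were below them (each permutation adjusted p = 0.00233). Many of these RNAs have near-identical gene copies, and how the authors placed reads shared between them is not given in the sources used here.

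The stretch of chromosome X around nhr-28 without a pooled summit measured 56.1 kb, from 16332102 to 16388248, and 11 of the 6015 such stretches on X were longer, against a median of 1.18 kb. It measured 52.8 kb in replicate 1 and 57.4 kb in replicate 2. The stretch at unc-119 on III measured 42.7 kb in the pooled list, with 18 of 4463 longer, 55.5 kb in replicate 1 and 11.4 kb in replicate 2. The pooled stretch began at a summit at 10903928 and that of replicate 2 at 10905323. Both summits lay within unc-119, so these stretches did not span the gene.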
